A study of Mus musculus with 24 samples.

How the data were processed

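Polyadenylated RNA of 24 retinal organoid samples was sequenced from stranded libraries with paired-end reads, per the labels' protocols. The libraries were placed in 9 groups by the culture method and day in their titles, 3 groups of 2 and 6 of 3, and replicate numbers were taken from the same titles. The series' design text calls the repeated experiments biological replicates. Per the labels' protocols, serum, B27 supplement and amino acids were added from D18 in SSCd and RWB and from D26 in SSCi. The labels mention 2 embryonic stem cell clones without saying which sample came from which.

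The submitters' processing notes name kallisto 0.42.5, edgeR 3.13.9, limma 3.32.2 and the genome build GRCm38.p5, with no role or order. How transcripts were combined into genes and the annotation release are not given in the sources used here. The deposited gene table holds estimated counts that are not normalized, for 33846 genes, and 42.1% of its values are whole numbers. Each library's total in it equals its total in the deposited table of estimated counts for 105129 transcripts. Another deposited table, treated here as a score, holds for 15396 genes the CPM of the gene table times 1 constant per library, between 0.9 and 1.25. It was used only for that check. Genes with near-identical copies share reads in such estimates, so their values are uncertain.

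The estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr by group, which left 16792, and libraries were scaled by TMM. A quasi-likelihood fit in edgeR 4.0.16 under R 4.3.3 (robust, 9 group means, all 24 libraries, median biological coefficient of variation 0.276) gave each comparison its F-test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All groups entered 1 fit because groups of 2 or 3 give a poor estimate of the spread on their own. CPM are TMM-scaled, log2 CPM have a prior count of 2, and standard errors are the log2 fold change over the root of F. Total counts per library ranged from 13284632 to 21604446, and within groups, over genes averaging at least 100 counts, libraries differed by 10.1 to 241 times the variance of counting alone, so none was treated as a repeat deposit. No fold is given for a gene with 3 or fewer raw counts in a group. Gene symbols were found for 33331 IDs, and positions come from GENCODE M21 on GRCm38.

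Before the data were examined, 13 comparisons, 35 gene lists (594 genes, 592 of them in the table) and the alternatives were fixed, except those named as added. Each list with at least 5 tested members was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 455 tests camera called 195, and 29 calls were made with an estimated correlation. Some genes are on several lists and count in each. Among them are Gnb3 (cone and bipolar), Isl1 (ganglion cell and bipolar) and Tfap2c (amacrine and surface epithelium). The rod list mean per library was compared between RWB and SSCd at D22 by a two-sided exact permutation test. Genes are named by a rule. It takes up to 5 genes with the highest and 5 with the lowest log2 fold change among those called, with a mean log2 CPM of at least 3 and no overlap between the libraries of both groups. It adds a panel of 16 genes, and up to 4 members of each called list with the smallest p in the list's direction. Further members were named because a count was 5 or fewer or because they moved against their list, and these were chosen after their values were seen. From the genes the rule allows, the text gives a selection, and some of them are not reported here.

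Same-numbered libraries were checked for deviating together, asking for at least 3 pairs and a correlation of deviations from group means over 0.1 in every pair. This held between RWB D22 and SSCd D22 (0.43, 0.20 and 0.43), between SSCd D18 and D22 (0.41, 0.12 and 0.33), and between RWB D22 and RWB D25, each of these RWB groups and SSCd D18, RWB D25 and SSCd D22, and SSCd D22 and D28. RWB D18, SSCi D18 and SSCi D25, with 2 libraries each, could not meet it whatever their values, so for them it decides nothing. It did not hold for SSCi D32, between SSCd D18 and D28, or between SSCd D28 and RWB D22 or D25. The pairing rests on this check, since no label says what a number shares.

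The test was run once per comparison on simulated counts with 200 changed genes, drawn from those with a mean log2 CPM above 1. It recovered 31% of 2-fold and 95% of 4-fold changes for RWB against SSCd at D22, 16% and 84% at D18, 21% and 90% for RWB against SSCi at D25, 29% and 87% for RWB D25 against SSCd D28, and 3% and 49% for the difference in change between RWB and SSCd. In the same order, 4 of 130, 4 of 104, 2 of 113, 10 of 126 and 2 of 54 calls were false. Counts were drawn independently for each library, so deviations shared by replicate number were not simulated. Recovery of changes in genes of lower expression was not simulated either. Alternatives were size factors by RLE, no filter on low counts, a replicate block, a fit of only the groups compared, limma-voom, DESeq2 1.42.0, fry in place of camera, and leaving out each library in turn, where a group left with 1 library takes the spread of the others. Added after seeing the data were transcript counts summed per gene (103635 transcripts assigned, 99.31% of counts), a fit without the RWB and SSCd libraries numbered 1, a replicate block in 5 groups, and 2 blocks in the D18 groups of RWB and SSCi. No group held 4 or more libraries, so single libraries were not tested as outliers.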

Results

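Bulk polyadenylated RNA was sequenced from retinal organoids grown from mouse embryonic stem cells under 3 culture methods. Organoids were kept intact in static suspension (SSCi), or their optic cups were dissected and kept in static suspension (SSCd) or in a rotating-wall bioreactor (RWB), a turning vessel that holds tissue in suspension. The 24 libraries formed 9 groups. RWB had 2 libraries at day 18 (D18), 3 at D22 and 3 at D25. SSCd had 3 each at D18, D22 and D28, and SSCi had 2 at D18, 2 at D25 and 3 at D32. Total estimated counts per library ranged from 13284632 to 21604446. Mitochondrially encoded genes took 10.2% and 13.1% of counts in replicate 1 of RWB D22 and D25, and 9.57% and 8.26% in replicate 1 of SSCd D18 and D22. The other 20 libraries lay between 2.46% and 5.76%.

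Rotation was compared with static culture of dissected optic cups at D22, the later of the days that both methods share. Gnat2, the cone transducin alpha subunit, was higher in RWB, at 139 ± 52.6 CPM (SD, n = 3) against 20.9 ± 10.0 CPM in SSCd (n = 3), a log2 fold change of 2.73 (SE 0.46, edgeR adjusted p = 0.0038). The cone channel subunits Cngb3 (1.93, edgeR adjusted p = 0.010) and Cnga3 (2.41, edgeR adjusted p = 0.0055) rose with it. Several rod genes were lower, among them the phosphodiesterase subunit Pde6b (-2.50), the exchanger Slc24a1 (-3.08), the retinoid carrier Rbp3 (-2.06) and the matrix proteoglycan Impg2 (-1.26), each at an edgeR adjusted p of at most 0.0072. Of 27 hypoxia and glycolysis genes 11 were lower (list adjusted p = 0.0889 with an estimated correlation). Aldoc fell by 2.30, Pdk1 by 2.26, Pgk1 by 1.43 and Aldoa by 1.42 on the log2 scale.

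Of the 30 rod genes listed before the data were examined, 9 fell at D22 and 1 rose, or 16 and 1 adjusted over the list alone. The riser was Guca1a (2.54), a guanylate cyclase activator of cones as well as rods. The list was not limited to genes absent from cones, so it is not a measure of rods alone. The list was lower by camera (adjusted p = 2.25e-11; adjusted p = 0.282 with an estimated correlation). Nrl (-1.19), Nr2e3 (-1.35), Gnat1 (-0.43), Sag (-0.36) and Crx (-0.26) were not called, and without SSCd replicate 1 Sag stood at 0.28 and Crx at 0.04. With a replicate block edgeR called Nrl (-1.08, adjusted p = 0.0488), and with the block in 5 groups, chosen after seeing the data, Nrl (-1.05, 0.0267) and Nr2e3 (-1.19, 0.0487). Averaged over the rod list, log2 CPM was 5.90 ± 0.29 in RWB and 6.84 ± 0.82 in SSCd (SD, n = 3 each). The difference of -0.94 did not pass (two-sided exact permutation p = 0.2, where 0.1 is the smallest possible), and without SSCd replicate 1 it was -0.51. Within the numbers 1, 2 and 3 it was -1.67, -0.65 and -0.51 (exact paired permutation p = 0.25, the smallest that 3 pairs allow). Of 15 cone genes, 3 rose and 1, Kcne2 (-2.61), a potassium channel subunit also on the choroid plexus list, fell, or 5 and 1 adjusted over the list alone. The cone list was higher by camera (adjusted p = 3.5e-05; adjusted p = 0.282 with an estimated correlation). Opn1sw (1.25) and Arr3 (0.71) were not called.

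The 11 hypoxia and glycolysis genes that fell at D22 were 23 when adjusted over the list alone, with a median log2 fold change of -1.42 (camera adjusted p = 2.53e-24; adjusted p = 0.0889 with an estimated correlation). Of 12 retinoic acid genes, Cyp26b1 (-2.86), which degrades retinoic acid, and Dhrs3 (-1.98), fell, or 4 adjusted over the list alone. That list had a camera adjusted p of 0.0166 (adjusted p = 0.142 with an estimated correlation), and 0.0771 without RWB replicate 3. The mitochondrially encoded list was higher (median 0.54, 0 of 13 called by edgeR over all genes or adjusted over the list alone, camera adjusted p = 0.0217; adjusted p = 0.851 with an estimated correlation), a call lost without RWB replicate 1 (adjusted p = 0.569), SSCd replicate 2 (0.195) or SSCd replicate 3 (0.456). The libraries numbered 1 held the largest mitochondrial shares of both groups, 10.2% in RWB and 8.26% in SSCd. The dorsal transcription factor Tbx5 (-1.84) and the epithelial keratin Krt18 (-2.54, and -3.57 without RWB replicate 3) also fell. Of 30 cell cycle genes, Mcm5 (1.17) and Tyms (1.28) rose, or 10 adjusted over the list alone (camera adjusted p = 6.49e-12; adjusted p = 0.282 with an estimated correlation). In all, 68 genes were higher and 250 lower among 16792 tested. Left-out libraries moved this count of 318 to 143 (RWB replicate 1), 98 (RWB replicate 2), 153 (SSCd replicate 1) and 185 (SSCd replicate 2), a replicate block in 5 groups gave 149 higher and 386 lower, and without both libraries numbered 1 it was 81. A fit of these 6 libraries called 125 and DESeq2 669. Of the 19 called genes named for D22, 12 kept the call whichever library was left out, while Mcm5, Tyms, Tbx5, Impg2, Cngb3, Dhrs3 and Guca1a did not: 6 calls were lost without RWB replicate 1, 7 without replicate 2 and 2 without replicate 3, and 3, 3 and 4 without SSCd replicates 1, 2 and 3.

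**Figure D1:**
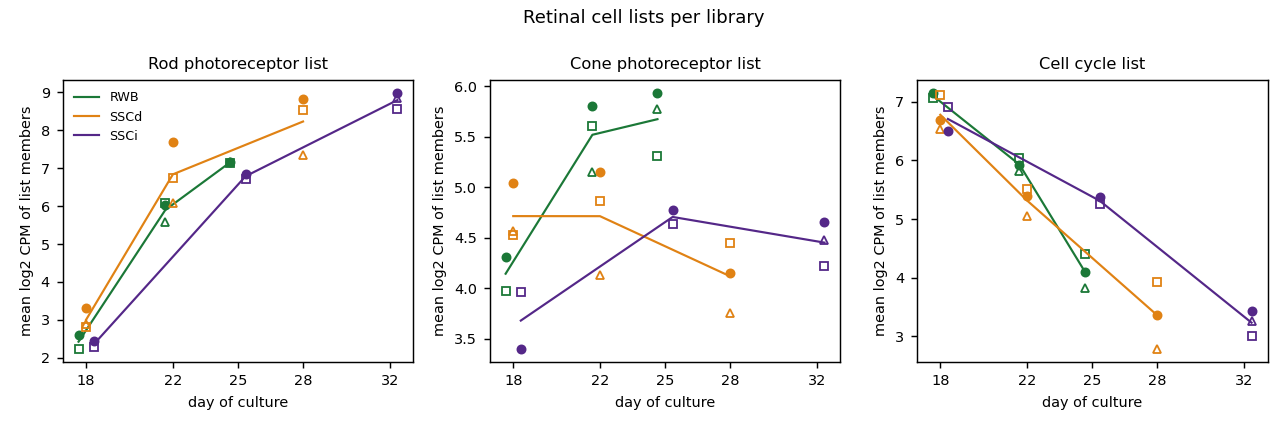
Mean log2 CPM of the tested members of the rod, cone and cell cycle lists (y axes) against day of culture (x axes) for each library. Points are libraries (circle replicate 1, square replicate 2, triangle replicate 3), lines join group means, and groups of 1 day are drawn side by side. The rod list mean rose from 2.42 to 7.16 in RWB between D18 and D25, and the cone list mean was 5.68 in RWB at D25 and 4.12 in SSCd at D28.

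At D18 the same methods differed in fewer genes, 12 higher and 70 lower in RWB. Hypoxia and glycolysis genes were again lower: Pdk1 (-2.45), Pgk1 (-1.43), Aldoa (-1.48) and Aldoc (-2.01) were among 6 of 27 that fell, or 16 adjusted over the list alone, with a median of -1.38 (camera adjusted p = 1.03e-23; adjusted p = 0.0968 with an estimated correlation). Pdk1 had 42.8 ± 3.11 CPM in RWB (SD, n = 2) and 234.3 ± 37.5 CPM in SSCd (n = 3). Cpt1a, the carnitine transferase of mitochondrial fatty acid import, rose by 2.37 (edgeR adjusted p = 0.0024), and Mest (1.42), Pcsk2 (1.45) and Etv5 (1.35) rose too. Among rod genes Prph2 (-2.78) and Samd7 (-2.85, and -3.57 without RWB replicate 2) fell, 2 of 30, or 5 adjusted over the list alone (camera adjusted p = 0.000203; adjusted p = 0.740 with an estimated correlation). The cone list was lower as well at this day (camera adjusted p = 0.00183; adjusted p = 0.417 with an estimated correlation), with Kcne2 (-3.21) its 1 fallen member of 15, or 1 adjusted over the list alone, and its adjusted p was 0.0594 without RWB replicate 2. The synaptic calcium channel subunit Cacna2d4 fell by 2.19. Nrl (-1.68), Mki67 (0.33) and Pou4f2 (1.40) were not called. The count of 82 was 20 without RWB replicate 1, 0 without RWB replicate 2, 17 without SSCd replicate 1, 29 without SSCd replicate 3 and 36 without the libraries numbered 1. The 12 called genes named here lost 8 calls without RWB replicate 1, 12 without RWB replicate 2, 8 without SSCd replicate 1 and 3 without SSCd replicate 3. Without RWB replicate 2, which left 1 RWB library, edgeR had about as many genes at an unadjusted p under 0.05 as chance alone gives. A fit of these 5 libraries alone also called 0 in edgeR, with 1193 of 15051 genes at an unadjusted p under 0.05. Chance alone gives 840 of 16792 in the main fit. On all libraries limma-voom called 54 and DESeq2 258.

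Whether the change from D18 to D22 differed between RWB and SSCd was tested as an interaction. The cone list rose more in RWB, with a median difference of 0.98 (camera adjusted p = 4.13e-16; adjusted p = 0.0200 with an estimated correlation). Its members Pde6h (3.65), Gnat2 (2.48), Opn1sw (2.34) and Arr3 (1.93) were among 8 of 15 called adjusted over the list alone, though none passed over all genes. The mean of the cone list went from 4.14 to 5.52 in RWB and stayed at 4.71 in SSCd. For single genes edgeR called 0 of 16792, with 525 at an unadjusted p under 0.05, where chance alone gives 840. DESeq2 called 12 and limma-voom 0. The simulated data, with no change placed in genes of low expression, recovered 49% of 4-fold and 3% of 2-fold differences of this kind.

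Time within each culture was followed next, and the medium changed over the same days. Serum and supplements were added from D18 in RWB and SSCd and from D26 in SSCi. Day and medium therefore cannot be told apart in these comparisons. In RWB, the rod genes Nrl (5.12), Nr2e3 (6.20), Prph2 (5.76), Samd7 (6.14) and Pde6b (6.50) rose from D18 to D22, and 22 of 30 rod genes did, or 28 adjusted over the list alone (camera adjusted p = 7.70e-32; adjusted p = 0.0667 with an estimated correlation). Opn1sw (3.92), Arr3 (2.72) and Gnb3 (1.70) rose among 7 of 15 cone genes, while Thrb (-1.01) fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 2.88e-05; adjusted p = 0.166 with an estimated correlation). Atoh7, which specifies ganglion cells, fell by 3.76, Fgf15 by 4.13, Ccnd1 by 1.87 and the ganglion cell factor Pou4f2 by 4.37. Of 24 synapse genes 17 rose, or 20 adjusted over the list alone, and this list kept its call with an estimated correlation (adjusted p = 0.00925). In all 1009 genes rose and 820 fell. This count of 1829 was 365 without RWB D18 replicate 2 and 1106 without RWB D22 replicate 1. Thrb lost its call without any 1 of the 5 libraries and Arr3 without RWB D18 replicate 2. Without that replicate 2 Pde6b stood at 7.67 and Samd7 at 6.85, and without RWB D18 replicate 1 Pde6b stood at 5.87.

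By D25, 29 of the 30 rod genes had risen in RWB, with the same count adjusted over the list alone. Nr2e3, a nuclear receptor of rods, went from 2.58 ± 0.21 CPM (SD, n = 2) at D18 to 308.2 ± 6.57 CPM (n = 3) at D25 (log2 fold change 6.90, SE 0.66, edgeR adjusted p = 3.6e-07), and Nrl rose by 5.83. The rod, bipolar and synapse lists were higher, and the cell cycle (median -3.12), retinal progenitor (-2.26), neurogenic progenitor (-2.22) and ganglion cell (-2.09) lists lower, and these 7 calls held with an estimated correlation. Of 23 bipolar genes 12 rose and Trpm1 (-2.09) and Isl1 (-2.13) fell, or 13 and 2 adjusted over the list alone, and of 20 ganglion cell genes 16 fell and Nefh (3.93) rose, or 17 and 1. Mki67 fell by 3.79, Atoh7 by 7.77 and Pou4f2 by 7.21, while Prkca, a kinase of rod bipolar cells, rose by 1.64 and Rlbp1, a Mueller glia gene, by 2.34. In all 2508 genes rose and 2347 fell. This count of 4855 was 3014 without RWB D18 replicate 2 and 2488 in a fit of these 5 libraries, and Trpm1 lost its call without that library (-1.01) or without RWB D25 replicate 2 or 3. Without RWB D25 replicate 2 Atoh7 stood at -8.42, while the 2 remaining libraries had 0 and 0.107 CPM of Pou4f2, too few for a fold, and without RWB D25 replicate 1 Trpm1 stood at -2.81.

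In SSCd, 28 of 30 rod genes rose from D18 to D22, or 29 adjusted over the list alone, with a median of 4.23 (camera adjusted p = 2.64e-43; adjusted p = 0.0206 with an estimated correlation). Pde6b rose by 7.83, Nr2e3 by 5.48 and Nrl by 4.63, or 3.95 without SSCd D22 replicate 1. All 30 cell cycle genes fell, also adjusted over the list alone (camera adjusted p = 6.89e-27; adjusted p = 0.0712 with an estimated correlation). The cone list was not called (camera adjusted p = 0.741, direction down, median log2 fold change -0.08, mean 0.09): Opn1sw (1.57), Gnb3 (0.81) and Kcne2 (4.70) rose, and Gnat2 (-1.42), Cnga3 (-1.87), Cngb3 (-1.22) and Thrb (-1.61) fell, also adjusted over the list alone. Of 22 sterol synthesis genes 17 fell, with the same count adjusted over the list alone, including Hmgcs1 (-1.32), Acat2 (-1.14) and Nsdhl (-1.27), and that call held with an estimated correlation (adjusted p = 0.0237). In all 1214 genes rose and 862 fell. This count of 2076 was 1142 without SSCd D18 replicate 2 and 1313 without SSCd D22 replicate 1. Same-numbered libraries of these groups deviated together, and a replicate block gave 2579. Gnat2, Cngb3, Opn1sw and Gnb3 lost their calls in 2 to 4 at a time for each of the 6 libraries left out, and camera's direction for the cone list turned upward without SSCd D18 replicate 1 (list mean difference 0.17) or SSCd D22 replicate 3 (0.29).

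From D18 to D28 all 30 rod genes rose in SSCd (median 5.39; estimated correlation adjusted p = 0.0345) and all 30 cell cycle genes fell (median -3.53; estimated correlation adjusted p = 0.0345), with the same counts adjusted over the list alone. Gnat1 rose by 5.03, Grm6 by 6.34 and the bipolar factor Vsx1 by 5.83. Opn1sw (-0.48) and Arr3 (0.95) were not called. Bipolar genes rose in 18 of 23 cases and Isl1 (-0.90) fell, or 19 and 2 adjusted over the list alone (adjusted p = 0.0180 with an estimated correlation), and sterol synthesis genes fell in 19 of 22, the same adjusted over the list alone (adjusted p = 0.0417 with an estimated correlation). In all 2944 genes rose and 2865 fell, and Isl1 lost its call without SSCd D18 replicate 2 or 3 or SSCd D28 replicate 1.

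In SSCi from D18 to D32 all 30 rod genes rose, the same adjusted over the list alone (adjusted p = 0.0395 with an estimated correlation). Nr2e3 went from 7.29 ± 5.28 CPM (SD, n = 2) to 740.2 ± 61 CPM (n = 3), a log2 fold change of 6.66, and Nrl rose by 5.83. Grm6, the glutamate receptor of ON bipolar cells (8.37), Rlbp1 (4.59) and Calb1, a calcium-binding protein of horizontal cells (3.91), rose, while Atoh7 (-8.84), Fgf15 (-7.89) and Ccnd1 (-3.62) fell. Of 15 mesenchyme genes 14 fell, the same adjusted over the list alone (camera adjusted p = 0.00128; adjusted p = 0.440 with an estimated correlation). Their D18 level lay in 1 of the 2 D18 libraries: Col1a2 had 1920 CPM in replicate 1 and 5.54 CPM in replicate 2. Without that replicate 1 the list was not called (camera adjusted p = 0.604) and Col1a2 stood at 0.30, Grm6 at 7.74 and Nr2e3 at 7.68. Without D18 replicate 2 Col1a2 stood at -8.07 and Atoh7 at -8.20. In all 2721 genes rose and 3445 fell.

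Dissection was addressed by SSCd against SSCi at D18, with 59 genes higher and 590 lower in SSCd. Gnat2 (2.08), Gnb3 (1.24), Ccdc136 (0.78) and Cngb3 (1.65) rose among 15 cone genes, or 7 adjusted over the list alone (camera adjusted p = 5.67e-10; adjusted p = 0.0597 with an estimated correlation). Gad1, a GABA-synthesising enzyme of amacrine cells (1.96), and the synaptic protein Snap25 (1.42) were also higher. The lower genes included collagens and matrix genes, with 10 of 15 mesenchyme genes fallen, or 13 adjusted over the list alone (camera adjusted p = 7.07e-09; adjusted p = 0.193 with an estimated correlation), among them Tagln (-5.51), Col1a2 (-7.58) and Postn (-7.27). These transcripts were abundant in SSCi D18 replicate 1 alone: Postn had 1034 CPM there and 3.73 CPM in replicate 2, and without that library the list mean turned to 0.30 (camera adjusted p = 0.679), Col1a2 stood at -0.14, Postn at -0.15 and Tagln at -0.76. Bmp4 (-5.08) and Aldh1a1 (-2.22) fell among 8 dorsal retina genes, or 4 adjusted over the list alone (camera adjusted p = 4.96e-05; adjusted p = 0.113 with an estimated correlation), and stood at -1.07 and -1.55 without SSCi replicate 1. Without SSCi replicate 2 Col1a2 stood at -8.52, Postn at -8.21, Tagln at -6.42 and Bmp4 at -5.98, and without SSCd replicate 1 Postn stood at -8.10 and Bmp4 at -5.71. The count of 649 was 0 without SSCi replicate 1, 1339 without SSCi replicate 2, 380 without SSCd replicate 1, 92 without SSCd replicate 2, 0 without SSCd replicate 3 and 0 without the RWB and SSCd libraries numbered 1 (2595 at an unadjusted p under 0.05). The 11 called genes named here all lost their calls without SSCi replicate 1 or SSCd replicate 3, and 6, 2 and 1 did without SSCd replicate 2, SSCd replicate 1 and SSCi replicate 2. Without SSCi replicate 1, which left 1 SSCi library, edgeR had fewer genes at an unadjusted p under 0.05 than chance alone gives. It had 1778 of 16779 without SSCd replicate 3 and 1283 of 15367 in a fit of these 5 libraries, which called 0. Chance alone gives 840 of 16792 in the main fit. On all libraries limma-voom called 28 and DESeq2 957.

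RWB against SSCi at D18 gave 153 genes higher and 725 lower in RWB. Hypoxia and glycolysis genes fell in 14 of 27 cases, or 24 adjusted over the list alone, with a median of -1.68 (camera adjusted p = 2.04e-21; adjusted p = 0.135 with an estimated correlation), including Pdk1 (-2.88), Pgk1 (-1.68), Aldoa (-1.74) and Car9 (-4.45). Gnat2 (2.33) and Cngb3 (1.89) were higher and Kcne2 (-4.18) lower among 15 cone genes, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0154; adjusted p = 0.442 with an estimated correlation; camera adjusted p = 0.147 without RWB replicate 1 and 0.392 without SSCi replicate 1), and the bipolar gene Cabp5 (4.21) was higher. Cyp26b1 (-4.03), Rarb (-1.59) and Dhrs3 (-2.02) were lower among 12 retinoic acid genes, or 4 adjusted over the list alone (camera adjusted p = 0.0199; adjusted p = 0.255 with an estimated correlation; camera adjusted p = 0.105 without RWB replicate 2 and 0.106 without SSCi replicate 2). Tbx5 (-2.73), Nr2f2 (-1.60), Aldh1a1 (-3.34) and Bmp4 (-5.18) were lower among 8 dorsal retina genes, or 6 adjusted over the list alone (camera adjusted p = 1.35e-07; adjusted p = 0.135 with an estimated correlation). Without SSCi replicate 1, where Bmp4 had 64.0 CPM against 2.03 in replicate 2, Bmp4 stood at -1.17 (edgeR adjusted p = 0.784), Aldh1a1 at -2.67 (0.0923) and Dhrs3 at -0.91 (0.633), while Cabp5 stood at 3.43 and Cyp26b1 at -3.12. Without SSCi replicate 2 Cabp5 stood at 5.82 and Bmp4 at -6.09, and without RWB replicate 1 Cyp26b1 stood at -4.72. Mesenchyme genes fell in 11 of 15 cases, or 13 adjusted over the list alone (camera adjusted p = 1.35e-07; adjusted p = 0.340 with an estimated correlation), against the same single SSCi library, without which the list was not called (camera adjusted p = 0.417). The count of 878 was 83 without SSCi replicate 1, 1446 without SSCi replicate 2, 64 without RWB replicate 1, 34 without RWB replicate 2 and 160 without the RWB and SSCd libraries numbered 1. Of the 15 called genes named here, 11 lost the call without RWB replicate 1, 13 without RWB replicate 2, 8 without SSCi replicate 1 and 1 without SSCi replicate 2. An edgeR fit of these 4 libraries called 0, with 1460 at an unadjusted p under 0.05, limma-voom on all libraries 374 and DESeq2 1376.

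RWB and SSCi were also matched at D25, a comparison in which the medium differed as well, since serum and supplements were added from D18 in RWB and from D26 in SSCi. Ccnd1 fell by 2.84, Sfrp2 by 3.62, Sox2 by 1.09, Neurog2 by 1.67 and Mki67 by 1.91 on the log2 scale. Of the lists, 10 of 16 retinal progenitor, 11 of 15 neurogenic and 20 of 30 cell cycle genes fell, or 13, 12 and 26 adjusted over the list alone, where 1 cell cycle gene also rose. Their camera adjusted p values were 4.63e-12, 9.19e-12 and 2.04e-15, against an adjusted p of 0.0556, 0.0556 and 0.186 with an estimated correlation. Genes of the respiratory chain rose in 15 of 36 cases, or 29 adjusted over the list alone (camera adjusted p = 1.74e-13; adjusted p = 0.423 with an estimated correlation), among them Ndufa1 (1.84), Cox8a (1.27) and Ndufa4 (2.54). RWB D25 replicate 1, the library with 13.1% mitochondrial counts, belongs to this group, and without it Cox8a and Ndufa4, then at 1.50, were not called. Without SSCi replicate 1 or 2 the edgeR adjusted p was 0.0678 and 0.118 for Ndufa1, 0.138 and 0.0906 for Cox8a and 0.0875 and 0.196 for Ndufa4, and Sox2 was at 0.0717 without SSCi replicate 2.

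Of the photoreceptor genes at D25, Gnat2 (3.58), Slc24a2 (3.47), Arr3 (1.90) and Pde6h (2.55) were higher in RWB among 5 of 15 cone genes and Ccdc136 (-1.06) was lower, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.00998; adjusted p = 0.451 with an estimated correlation). Guca1a (5.23) and Gnat1 (3.07) rose among 5 of 30 rod genes, and Rbp3 (-2.47), Kcnv2 (-1.64) and Impg2 (-1.13) fell, or 6 and 3 adjusted over the list alone, and that list was not called (camera adjusted p = 0.512). Nrl (-0.41), Crx (0.34) and Opn1sw (0.06) were not called, and Opn1sw stood at -0.03 without RWB replicate 2 and -0.13 without RWB replicate 3. Grm6 (3.74), Prkca (1.40) and Lhx4 (2.61) rose among 5 of 23 bipolar genes and Rgs11 (-3.02) fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0225; adjusted p = 0.221 with an estimated correlation; camera adjusted p = 0.126 without RWB replicate 3), and Gfap, the glial filament, rose by 5.01. Epcam (-3.60), Krt18 (-2.50), Cdh1 (-1.68) and Tfap2c (-0.71) fell among 8 surface epithelium genes, the same 4 in number adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 0.0212). Cyp26b1 (-4.54), Crabp2 (-2.43), Tbx5 (-2.67) and Nr2f2 (-1.68) were lower. In all 605 genes were higher and 853 lower, and without the low-count filter 368 were higher. This count of 1458 was 624 without RWB replicate 1, 598 without SSCi replicate 1 and 251 without SSCi replicate 2, and a fit of these 5 libraries called 90, DESeq2 2409 and the fit without RWB and SSCd libraries numbered 1 called 810. Of the 31 called genes named for D25, 18 kept the call whichever library was left out, with 5 lost without RWB replicate 1, 2 without RWB replicate 2, 11 without SSCi replicate 1 and 12 without SSCi replicate 2. Slc24a2, Arr3, Pde6h, Gnat1, Gfap, Cdh1 and Tfap2c each lost the call without either SSCi library, with edgeR adjusted p up to 0.291 for Pde6h and 0.0591 and 0.156 for Gfap. Pde6h lost it also without RWB replicate 1, Cdh1 and Tfap2c without RWB replicate 1 or 2, Impg2 without SSCi replicate 1 and Krt18 without SSCi replicate 2. Without RWB replicate 1 Gnat2 stood at 2.91 and Slc24a2 at 2.44, and Gfap stood at 3.72 without RWB replicate 3 and 5.74 without SSCi replicate 1.

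**Figure D2:**
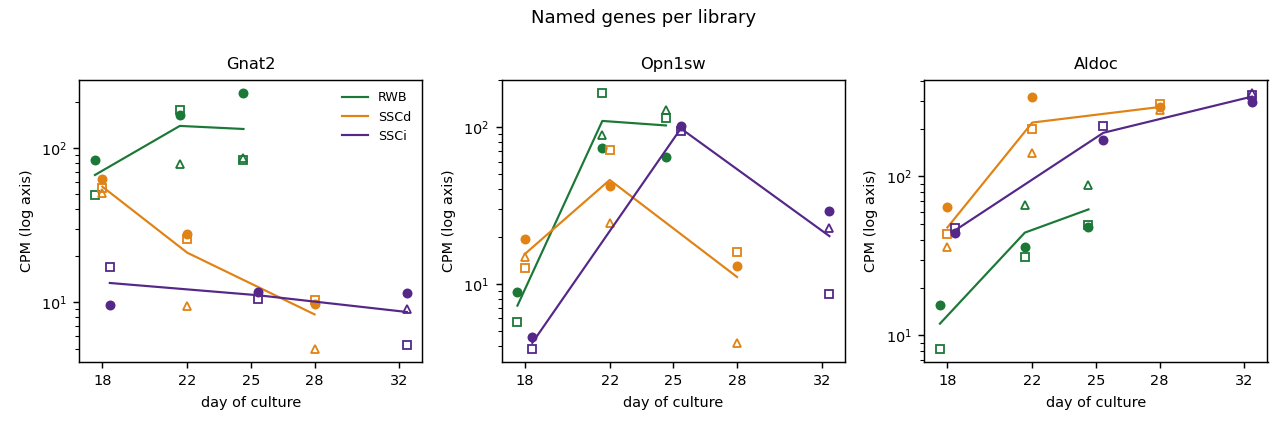
CPM on log y axes against day of culture (x axes) for Gnat2, Opn1sw and Aldoc in each library. Points are libraries (circle replicate 1, square replicate 2, triangle replicate 3) and lines join group means. Gnat2 stood at 132.8 CPM in RWB at D25, 8.34 CPM in SSCd at D28 and 8.64 CPM in SSCi at D32.

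The last days of each culture were then compared, with age differing along with method. Against SSCd D28, RWB D25 had higher cone genes: Gnat2 (3.99), Opn1sw (3.21), Cngb3 (2.77), Pde6h (2.92) and Arr3 (2.04) were among 10 of 15 that rose, and Kcne2 (-2.22) fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 3.12e-11; adjusted p = 0.0527 with an estimated correlation). Opn1sw, the short-wavelength cone pigment, had 102.5 ± 33.8 CPM in RWB and 11.1 ± 6.12 CPM in SSCd (SD, n = 3 each). Of 30 rod genes, 10 fell and Guca1a (3.81) rose, or 18 and 1 adjusted over the list alone (camera adjusted p = 1.42e-11; adjusted p = 0.218 with an estimated correlation), with Slc24a1 (-3.64), Rbp3 (-2.28), Kcnv2 (-1.86) and Impg2 (-1.54) lowest in p. Nrl (-0.94) and Nr2e3 (-0.90) were not called. The bipolar genes Grm6 (-2.19), Scgn (-2.58), Rgs11 (-2.83) and Bhlhe23 (-4.67) were among 7 of 23 that fell, and Lhx4 (1.61) and Gnb3 (0.88), which is also on the cone list, rose, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.00104, adjusted p = 0.0931 with an estimated correlation). Gnat2 stood at 3.33 without RWB replicate 1, Guca1a at 4.54 without SSCd replicate 2, and Bhlhe23 at -5.53 without RWB replicate 3 and -3.79 without SSCd replicate 3.

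Against SSCd D28, surface epithelium genes fell in 3 of 8 cases, or 5 adjusted over the list alone, and kept the call with an estimated correlation (adjusted p = 0.00977); Krt18 fell by 2.98. Sterol synthesis genes were higher in 7 of 22 cases, or 13 adjusted over the list alone, including Hmgcs1 (0.98) and Nsdhl (1.01) (camera adjusted p = 4.40e-11; adjusted p = 0.0837 with an estimated correlation). Hypoxia and glycolysis genes were lower in 5 of 27, or 19 adjusted over the list alone, with Aldoc at -2.14 and Pfkp at -2.75 (camera adjusted p = 4.44e-14; adjusted p = 0.175 with an estimated correlation). In all 186 genes were higher and 327 lower. This count of 513 was 192 without RWB replicate 1, 305 without SSCd replicate 1 and 295 without SSCd replicate 2, and a fit of these 6 libraries called 39, DESeq2 1071 and the fit without libraries numbered 1 called 138. Of the 22 called genes named, 18 kept the call whichever library was left out, and Lhx4, Gnb3, Nsdhl and Pde6h did not, with 3 lost without RWB replicate 1 and 1, 2 and 2 without SSCd replicates 1, 2 and 3.

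Against SSCi D32, RWB D25 had lower Gnat1 (-1.64), Slc24a1 (-3.90), Rbp3 (-3.27) and Kcnv2 (-2.71), with 17 of 30 rod genes fallen and Guca1a (3.15) risen, or 24 and 1 adjusted over the list alone (camera adjusted p = 4.90e-15; adjusted p = 0.172 with an estimated correlation). Cone genes were higher in 9 of 15 cases and Kcne2 (-1.57) was lower, or 11 and 1 adjusted over the list alone (camera adjusted p = 8.63e-07; adjusted p = 0.122 with an estimated correlation). They included Gnat2 (3.94), Cngb3 (3.06), Gngt2 (2.39) and Opn1sw (2.35), and without RWB replicate 1 Gnat2 stood at 3.26, Cngb3 at 2.46 and Gngt2 at 1.61 (edgeR adjusted p = 0.0485). Bipolar genes fell in 10 of 23 cases and Lhx4 (1.14) rose, or 10 and 2 adjusted over the list alone, and this call held with an estimated correlation (adjusted p = 0.0244); Grm6 fell by 3.04 and Scgn by 3.21. Hypoxia and glycolysis genes fell in 12 of 27 cases, or 18 adjusted over the list alone (camera adjusted p = 3.36e-12; adjusted p = 0.172 with an estimated correlation), with Aldoc at -2.35, Egln3 at -2.88 and Pfkp at -2.65. Rlbp1 (-0.91) fell and Mki67 (1.24) rose. In all 798 genes were higher and 853 lower, and without the low-count filter 483 were higher. This count of 1651 was 681 without RWB replicate 1, and 812, 822 and 645 without SSCi replicates 1, 2 and 3, and a fit of these 6 libraries called 853, DESeq2 2507 and the fit without RWB and SSCd libraries numbered 1 called 793. Of the 18 called genes named here, 13 kept the call whichever library was left out, and Gnat1, Kcne2, Lhx4, Mki67 and Rlbp1 did not, with 4, 2 and 2 lost without RWB replicates 1, 2 and 3 and 5, 4 and 5 without SSCi replicates 1, 2 and 3. Mki67 stood at 0.75 without RWB replicate 2.

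**Figure D3:**
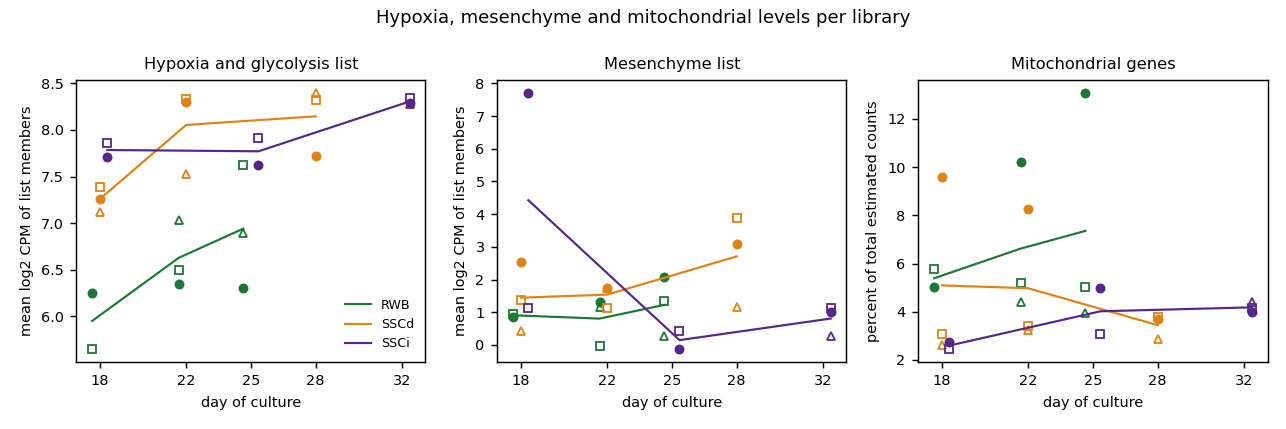
Mean log2 CPM of the hypoxia and glycolysis and mesenchyme lists, and the percent of estimated counts from mitochondrially encoded genes (y axes), against day of culture (x axes) for each library. Points are libraries (circle replicate 1, square replicate 2, triangle replicate 3) and lines join group means; the hypoxia list mean was 6.63 in RWB and 8.05 in SSCd at D22.

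Key genes lie at the following places in the mouse GRCm38 assembly by the GENCODE M21 annotation, all protein-coding. Gnat2 (ENSMUSG00000009108) spans 108092789 to 108101432 on chromosome 3 and Opn1sw (ENSMUSG00000058831) spans 29376671 to 29388468 on chromosome 6. On the same chromosome Cyp26b1 (ENSMUSG00000063415) spans 84571414 to 84593908. Aldoc (ENSMUSG00000017390) spans 78322968 to 78327781 on chromosome 11.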

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

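The tests of photoreceptor number, mesenchymal cells and a wrong label, and the setting without libraries numbered 1, were chosen after the result was seen, while the test of X escape genes was set before. The change from D18 to D22 differed between RWB and SSCd, by the interaction test, for 12 gene lists. Higher in RWB than in SSCd, by median log2 difference and camera adjusted p, were the changes of the cone (0.98, 4.13e-16), immediate early and heat shock (0.48, 0.000696), microglia and macrophage (2.01, 0.00123), sterol synthesis (0.27, 0.00123), synapse (0.25, 0.00299), cell cycle (0.35, 0.00328), horizontal cell (0.28, 0.00396), oxidative phosphorylation (0.25, 0.00875) and amacrine cell (0.47, 0.0119) lists. Lower were those of the rod (-0.81, 0.0119), p53 target (-0.43, 0.016) and ganglion cell (-0.36, 0.03) lists. For single genes edgeR called 0 (525 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 12. With an estimated correlation only the cone list of these 12 was called (adjusted p = 0.0200), while fry called none of the 12 and gave the cone list an adjusted p of 0.0667. The cone call held with each library left out. The microglia difference rested on RWB D22 replicate 2, with a list mean of 0.72 against -0.87 and -1.46 in the others, and without it fell from 1.16 to 0.67 by list mean.

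The other 11 calls each ended in at least 1 fit without a library (camera adjusted p in brackets). Without RWB D18 replicate 1 these were horizontal (0.0869), microglia (0.0869), p53 (0.0742) and rod (0.39). Without RWB D18 replicate 2 they were amacrine (0.278), immediate early (0.0657), oxidative phosphorylation (0.665), p53 (0.0539), ganglion cell (0.85) and sterol (0.112). For RWB D22 they were oxidative phosphorylation (0.947) and ganglion cell (0.0884) without replicate 1, microglia (0.0807), p53 (0.0807) and ganglion cell (0.066) without replicate 2, and amacrine (0.106), immediate early (0.142) and rod (0.236) without replicate 3. For SSCd D18 they were oxidative phosphorylation (0.293) and ganglion cell (0.593) without replicate 1, cell cycle (0.37), p53 (0.096) and rod (0.12) without replicate 2, and amacrine (0.289) and synapse (0.16) without replicate 3. For SSCd D22 they were amacrine (0.155), horizontal (0.0658) and rod (0.952) without replicate 1, oxidative phosphorylation (0.0671) and ganglion cell (0.181) without replicate 2, and cell cycle (0.145), oxidative phosphorylation (0.915), p53 (0.11) and sterol (0.11) without replicate 3.

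Hypoxia and glycolysis genes were lower in RWB than in SSCd by camera at D18 (median -1.38, adjusted p = 0.0968 with an estimated correlation) and D22 (median -1.42, adjusted p = 0.0889 with an estimated correlation). At D18 Pdk1, Pgk1, Aldoa and Aldoc lost their calls without RWB replicate 1, without RWB replicate 2 or without SSCd replicate 1. Aldoa lost it also without SSCd replicate 3. The tables argue against the libraries numbered 1, with their high mitochondrial shares, as the source at D22: without them the median was -1.18, and the remaining RWB libraries (list means up to 7.04) lay below the remaining SSCd libraries (from 7.53). At D18 the photoreceptor precursor list did not fall as far as the hypoxia list. It had a median of -0.09 and a lower quartile of -0.47, above the hypoxia upper quartile of -0.77. Fewer photoreceptors in RWB stay open at D18 all the same, since the precursor list does not count photoreceptors. Camera at the preset correlation called the rod and cone lists lower at that day. Rod genes had a median of -0.35 and a lower quartile of -1.14. At D22 fewer photoreceptors cannot be told apart from another cause either. There the precursor median was -0.17, but the rod list median of -1.12 lay below the hypoxia upper quartile of -1.04. The culture method itself may underlie the difference, as a hypothesis, and oxygen supply was not measured.

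Mesenchyme genes stood far higher in SSCi D18 replicate 1 than in replicate 2 (mean log2 CPM 7.72 against 1.14), and so, by less, did the extracellular matrix (7.80 against 4.99), microglia and macrophage (1.27 against -1.29), reactive glia (3.10 against 0.88) and vascular endothelium (1.31 against 0.07) lists. A library that is not retinal is argued against, since its retinal progenitor list mean (7.11) differed from that of replicate 2 (7.62) by only -0.5. The list members at least 4-fold higher numbered 14 of 15, among them Col3a1 (2040 against 3.33 CPM), Col1a2 (1920 against 5.54 CPM) and Col1a1 (975 against 5.31 CPM), where the other 22 libraries reached at most 96.9, 76.6 and 55.8 CPM. Mesenchymal cells in that library may be the source, as a hypothesis. Of 10 other transcripts abundant in mesenchyme, chosen after the result, 9 were also at least 4-fold higher. Among them were Sparc (2260 against 198 CPM), Fn1 (3800 against 158 CPM) and Bgn (1930 against 0.452 CPM). These 3 are on the extracellular matrix list, already given as higher, so they add no separate support. Serpinh1 was not 4-fold higher (544 against 415 CPM), and 7 of the 10 had 8 CPM or more in replicate 2 as well. No label names a sort or gate, cells of the other types listed were not tested, and the design names no group that separates these 2 libraries.

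Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty summed) differed by replicate number in 5 groups of RWB and SSCd, at 4.99 to 16.2 CPM in libraries numbered 1, 12.2 to 55.1 in those numbered 2 and 103 to 272 in those numbered 3, though in SSCd D28 number 1 (16.2) lay above number 2 (15.3). RWB D18 had 19.7 and 172 CPM, and SSCi libraries 47.7 to 232. A second X chromosome in libraries numbered 1 stays open: 4 genes that escape X inactivation differed by 0.06 on average (-0.07 to 0.20 over the groups), below the bound of 0.3 by 0.24, less than their range of 0.27. Loss of the Y chromosome in culture or a different cell line per number may also account for it, and culture and day, which each number spans, were not tested.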

How the results depend on the processing

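Transcript sums, the fit without the RWB and SSCd libraries numbered 1, the replicate block in 5 groups and both D18 blocks of RWB and SSCi were chosen after seeing the data. Over all alternatives, named genes kept direction and side of the threshold 2732 times, lost the call 475 times, gained it 13 times and turned 6 times, and lists did so 763, 127, 0 and 5 times. RLE size factors, no low-count filter and transcript sums moved no total count by over 1.5 times, but without the filter the genes higher in RWB went from 605 to 368 against SSCi at D25 and from 798 to 483 for RWB D25 vs SSCi D32. The fit of only the groups compared, with fewer libraries to estimate the spread, called 0 genes in edgeR for RWB vs SSCd at D18 (1193 at an unadjusted p under 0.05), 0 for SSCd vs SSCi at D18 (1283), 0 for RWB vs SSCi at D18 (1460), 125 for RWB vs SSCd at D22, 90 for RWB vs SSCi at D25, 2488 for RWB D25 vs D18, 39 for RWB D25 vs SSCd D28 and 853 for RWB D25 vs SSCi D32. With limma-voom the D18 counts were 54 for RWB vs SSCd, 28 for SSCd vs SSCi and 374 for RWB vs SSCi. DESeq2 called 258 and 669 for RWB vs SSCd at D18 and D22, 1376 and 2409 for RWB vs SSCi at D18 and D25, 1071 for RWB D25 vs SSCd D28, 2507 for RWB D25 vs SSCi D32, and 12 for the difference in change, where edgeR called 0 (525 at an unadjusted p under 0.05) and limma-voom 0 (439). Without the libraries numbered 1 the counts were 36 and 81 for RWB vs SSCd at D18 and D22, 0 for SSCd vs SSCi at D18 (2595 unadjusted), 160 and 810 for RWB vs SSCi at D18 and D25, 138 for RWB D25 vs SSCd D28 and 793 for RWB D25 vs SSCi D32. Camera with an estimated correlation called 29 of 455 list tests, against 195 with the preset and 149 by fry. The cause of these differences in count was not tested.

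The replicate block raised RWB vs SSCd at D18 from 82 to 136 and RWB vs SSCi at D25 from 1458 to 3348. The pairing check decides nothing for either, since each has a group too small for it. The block also raised RWB D25 vs SSCd D28 from 513 to 997 and RWB D25 vs SSCi D32 from 1651 to 2566. For RWB D25 vs SSCd D28 the block in 5 groups gave 1260. The check did not hold for either pair of groups. Where it held, the replicate block gave 460 for RWB vs SSCd at D22 and 2579 for SSCd D22 vs D18. The block in 5 groups gave 535 and 2862 in that order. With the crossed pairing as a block, RWB vs SSCi at D18 had 0 genes in edgeR (2055 at an unadjusted p under 0.05), and with the plain numbers 0 (918). The replicate block called Nrl in RWB vs SSCd at D18 (-1.82, adjusted p = 0.0195) and D22 (-1.08, 0.0488), and ended the bipolar call of RWB vs SSCi at D25 (0.0899) and the rod (0.39) and amacrine (0.0807) calls in the difference in change. The block in 5 groups called Nrl and Nr2e3 at D22 and Nrl in RWB D25 vs SSCd D28. Among the comparisons named for these calls, the pairing check held throughout only for RWB vs SSCd at D22. Over all 24 libraries the block changed no other call of a named gene or list.

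Leaving out 1 library gave 0 to 73 genes for RWB vs SSCd at D18, 98 to 310 at D22, 0 to 1339 for SSCd vs SSCi at D18, 34 to 1446 for RWB vs SSCi at D18, 251 to 2073 at D25, 365 to 1624 for RWB D22 vs D18, 3014 to 4671 for RWB D25 vs D18, 1142 to 1742 for SSCd D22 vs D18, 4574 to 5268 for SSCd D28 vs D18, 4379 to 5244 for SSCi D32 vs D18, 192 to 637 for RWB D25 vs SSCd D28, 645 to 2363 for RWB D25 vs SSCi D32 and 0 to 0 for the difference in change (348 to 875 unadjusted). List calls numbered 181 to 200, and the rod list mean of RWB minus SSCd at D22 was -1.32 to -0.51. Directions turned for Crx (0.04, lowest -0.52 over left-out libraries) and Sag (0.28, lowest -0.79) in RWB vs SSCd at D22 without SSCd replicate 1, Sag also without both libraries numbered 1 (0.36), and Opn1sw in RWB vs SSCi at D25 without RWB replicate 2 (-0.03) or 3 (-0.13, highest 0.28). They also turned for the cone list, by camera's direction, in SSCd D22 vs D18 without D18 replicate 1 (0.17) or D22 replicate 3 (0.29, lowest -0.22), mesenchyme in SSCd vs SSCi at D18 (0.30, lowest -6.22) and Col1a2 in SSCi D32 vs D18 (0.30, lowest -8.07), both without SSCi D18 replicate 1, and, in the difference in change, the rod list without SSCd D22 replicate 1 (0.06, lowest -0.74) and, by its mean alone, without the libraries numbered 1 (0.08), and, by camera's direction but not its mean, the ganglion cell list without RWB D18 replicate 2 (-0.05, lowest -0.73). The cause was not tested. Depth limits genes of low count, such as Pou4f2 with 15 raw counts over the 3 RWB D25 libraries.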

Other observations

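The tests of other splits of the libraries were set before the result was seen, and the gene groups described here were chosen from the fixed lists after it was seen. In SSCi serum and supplements were added from D26, so day and medium differ together between D18 and D32. From D18 to D32 in SSCi, genes of the synapse rose in 22 of 24 cases, or 23 adjusted over the list alone (camera adjusted p = 9.86e-19; adjusted p = 0.00455 with an estimated correlation). Among them were the vesicle protein Syt1 (2.86) and the photoreceptor calcium channel subunits Cacna2d4 (3.48) and Cacna1f (6.47). Of 23 bipolar cell genes 19 rose, or 20 adjusted over the list alone (2.66e-11; adjusted p = 0.00169 with an estimated correlation), such as Scgn (4.45) and Tmem215 (2.71). Of 10 horizontal cell genes 6 rose, by both adjustments (0.00678; adjusted p = 0.0486 with an estimated correlation), with Calb1 at 3.91, Sept4 at 1.91 and Lpl at 1.92, while Onecut2 fell (-0.78), a call lost without SSCi D18 replicate 2 (edgeR adjusted p = 0.103) or SSCi D32 replicate 2 (0.0555). Retinal progenitor genes fell in 14 of 16 cases, or 15 adjusted over the list alone (2.9e-10; adjusted p = 0.0486 with an estimated correlation), with Sfrp2 at -5.01 and Sox2 at -2.59. All 8 dorsal retina genes fell by both adjustments (0.00193; adjusted p = 0.21 with an estimated correlation), with Bmp4 at -6.22, Aldh1a1 at -2.56 and Tbx3 at -1.71. Without SSCi D18 replicate 1, the library high in mesenchyme genes, Bmp4 stood at -2.22 and Aldh1a1 at -1.90 (edgeR adjusted p = 0.0249 and 0.0265), and Sfrp2 at -4.11. Without SSCi D18 replicate 2 Bmp4 stood at -7.13.

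At the last day of each method, 16 of 30 cell cycle genes were higher in RWB D25 than in SSCi D32, or 20 adjusted over the list alone (camera adjusted p = 1.56e-11; adjusted p = 0.226 with an estimated correlation), with Ccnb1 at 1.94, Nusap1 at 1.39 and Ube2c at 1.25. Of 22 Mueller glia genes 6 were lower, or 8 adjusted over the list alone (4.13e-05; adjusted p = 0.115 with an estimated correlation), with Dkk3 at -0.87 and Gpr37 at -0.96. Of 24 synapse genes, Cplx2 (1.19) and Cplx3 (1.44) were higher and Cacna2d4 (-2.10), Cplx4 (-2.27), Slc17a7 (-1.36), Pclo (-0.65) and Dlg4 (-0.68) lower, or 2 and 10 adjusted over the list alone (0.0151; adjusted p = 0.387 with an estimated correlation), and the list lost its call without RWB D25 replicate 2 (0.0734). Of 10 horizontal cell genes Prox1 (-1.71), Slc4a5 (-1.21) and Tnr (-1.57) were lower, or 5 adjusted over the list alone (0.00891; adjusted p = 0.115 with an estimated correlation). Single libraries ended several of these gene calls. Without RWB D25 replicate 1 the edgeR adjusted p was 0.114 for Cplx3, 0.0804 for Pclo, 0.18 for Dlg4, 0.0834 for Slc4a5 and 0.162 for Tnr, and without RWB D25 replicate 2 it was 0.0517 for Slc17a7, 0.0718 for Dlg4, 0.0535 for Slc4a5 and 0.0847 for Tnr. Without SSCi D32 replicate 1 it was 0.0509 for Slc17a7, 0.11 for Dlg4, 0.0522 for Slc4a5 and 0.0703 for Tnr. Without SSCi D32 replicate 2 it was 0.0781 for Cplx3, 0.0644 for Pclo, 0.072 for Dlg4 and 0.0966 for Tnr, and without replicate 3 it was 0.0929 for Cplx3, 0.0547 for Slc17a7, 0.0612 for Pclo, 0.116 for Dlg4, 0.0856 for Slc4a5 and 0.0956 for Tnr.

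In RWB against SSCi at D25, 5 of 8 dorsal retina genes were lower, Nr2f2 (-1.68), Tbx5 (-2.67), Efnb2 (-2.43), Tbx2 (-1.67) and Efnb1 (-1.29), or 6 adjusted over the list alone (camera adjusted p = 8.26e-07; adjusted p = 0.0717 with an estimated correlation). Of 16 p53 target genes Ccng1 (1.67), Cdkn1a (1.61) and Eda2r (1.53) were higher, or 8, with 1 lower, adjusted over the list alone (7e-04; adjusted p = 0.186 with an estimated correlation). Without RWB D25 replicate 1, SSCi D25 replicate 1 and SSCi D25 replicate 2 in turn, the edgeR adjusted p was 0.0837, 0.0646 and 0.196 for Ccng1, 0.0726, 0.176 and 0.141 for Cdkn1a, 0.231, 0.183 and 0.3 for Eda2r, and 0.126, 0.0791 and 0.252 for Efnb1. Tbx2 was at 0.196 without SSCi D25 replicate 2.

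Camera called 4 lists in 0 of 13 comparisons: lens (0 at an unadjusted p under 0.05, 0 by fry), brain outside the retina (0 and 0), choroid plexus (1 and 0) and vascular endothelium (0 and 3), and 0 of these with an estimated correlation. Their levels were low, with group means of log2 CPM of at most 0.35, 1.05, 2.25 and 0.69 in that order. Only 8 of 16 lens and 6 of 10 endothelium genes were tested, so a missing call does not show equal levels.

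In fits of 6 libraries, each with 10 splits of them into groups of 3, the split by label was the 1 split with as many genes. It gave 125 genes for RWB vs SSCd at D22 (highest other split 1), 1390 for SSCd D22 vs D18 (1), 5196 for SSCd D28 vs D18 (0), 39 for RWB D25 vs SSCd D28 (0) and 853 for RWB D25 vs SSCi D32 (0). With 10 splits, a share under 0.05 cannot be reached.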
